A study of Mus musculus with 15 samples.

How the data were processed

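Gene expression was measured in total RNA of mouse micromass cultures on Affymetrix MOE430A arrays, 1 array for each of 3 replicates on days 3, 6, 9, 12 and 15, 15 arrays in all. Each array's day and replicate number were taken from its label. The deposited table gives 1 linear signal per probe set and array, with values at 0 on up to 5 probe sets of an array and a maximum between 3838 and 5882. The authors' scaling is visible in the deposited signal itself, because the mean after cutting 2% from each end was between 150.04 and 150.05 on every array. The algorithm that summarised the probes is not given in the sources used here, and calls of presence or absence were not used, so a low signal may be background. Scaling to an equal mean reports each gene relative to the rest of the array, so a change in the total RNA of a cell cannot be seen.

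The array experiment files supplied the chip lot, the fluidics module and the scan day, per the file headers, as settings and not as a measurement. The arrays came from 1 chip lot, were washed on 4 modules and were scanned on 5 days. The replicate 2 arrays were all scanned on one day, scan day 3. The arrays of replicate 1 lay on scan days 1 (days 3, 9 and 15) and 2 (days 6 and 12), and those of replicate 3 on scan days 4 (days 6, 12 and 15) and 5 (days 3 and 9). Each scan day thus held several days of culture, and results are given with scan day as a block and within scan days.

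Of 22690 probe sets, 64 control probe sets were left out and 22626 were tested with no filter on level. The supplied platform annotation gave 1 gene name for 20380 of these, several names for 691 and none for 1555, and only probe sets with 1 name are named. Of the single names, 20351 matched the supplied RefSeq gene table (assembly GRCm38.p6, used for names only) by gene identifier, and 0 symbols needed an update. The names cover 12393 genes, 4956 of them with more than 1 probe set. For a gene with several, the probe set with the highest mean was used, and disagreement of the others is given beside the named genes. The build used for the array annotation is not given in the sources used here, and no coordinates are given.

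Signals were analysed as log2(signal + 16). The array medians on this scale lay within 0.115 of one another, under the limit of 0.2 set beforehand, so that no further normalization was applied. Each probe set was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with day as a factor and no replicate block, over all 15 arrays, which leaves 10 residual degrees of freedom. The median standard error of a difference between 2 days was 0.156 on the log2 scale. A moderated F-test gave changes over the 5 days. Contrasts compared day 15 with day 3 and each day with the one before it. P-values were adjusted by the Benjamini-Hochberg method over probe sets within each test, at a threshold of 0.05, and a further count asked for a fold of at least 2. In this text an error after a signal is an SD over 3 arrays, and an error after a log2 change is the SE of the model.

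The comparisons, the tests, 34 gene lists, the markers, the rule for naming genes and the alternatives were fixed before the data were examined. The lists hold 864 entries, of which 764 were measured under a probe set with 1 name. Among the fixed markers, Spp1 and Runx2 were not analysed here. Lists were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the 170 tests of 34 lists in 5 comparisons, and again with a correlation estimated for each list and with fry. Beside each list stands the number of its genes that passed over all probe sets and adjusted over the list alone. The rule named, from day 3 to day 15, the 10 genes with the largest rise and the 10 with the largest fall, and 5 of each in each shorter interval. These genes had to pass the test, with every array of one day beyond every array of the other and a mean level on the higher day at or above the median of all probe sets. Up to 2 members with the highest and 2 with the lowest change were named from each list, and the fixed markers whatever their values.

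The same code was tested on simulated arrays in which 200 of 22626 probe sets were changed. These were drawn from probe sets with a mean at or above the median, so recovery among dimmer ones was not tested. From day 3 to day 15 it recovered 22.4% of simulated log2 changes of 0.5, 76.1% of changes of 1 and 98.5% of changes of 2, with 7 false calls. From day 12 to day 15 the shares were 22.4%, 88.1% and 100%, with 9 false calls. In the list test, 2 of 2 comparisons with a simulated shift of 0.5 were called and 0 of 165 without one. The simulated noise was independent between genes and between arrays. These counts therefore do not show how often lists of genes that vary together are called falsely.

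The alternatives were the replicate number as a block (fixed or random), quantile normalization, median centring, pseudocounts of 1 and 64, leaving out the dimmer probe sets, eBayes with a trend and robust fitting, scan day and fluidics module as blocks, only the 6 arrays of the days compared, other list tests, and leaving out each of the 15 arrays in turn. A contrast of day 15 with day 9 and a list of imprinted genes were added after the data had been seen, and they appear only in the closing observations.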

Results

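Total RNA from mouse micromass cultures was hybridised to 15 Affymetrix MOE430A arrays. A micromass culture is a small, very dense spot of cells, a format widely used to study the formation of cartilage in a dish. The arrays covered days 3, 6, 9, 12 and 15 of a time course, with 3 numbered replicates on each day. The labels do not name the tissue that gave the cells, and they do not say whether the replicates were separate cultures, so the p-values measure only the spread between these samples, which may be technical. The median signal per array ranged from 59.65 to 65.95 over 22626 probe sets, and the number of arrays, 3 a day, limits the precision of every comparison. The ratio of the 3' to the 5' probe set of beta-actin, a sign of RNA integrity, was 1.15 ± 0.0183 (SD, n = 3) on day 3 and 1.12 ± 0.0331 on day 15. All fold changes are on the log2(signal + 16) scale, which understates the change of genes with low signals.

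The time course addressed how gene expression in the cultures moved from day to day. Expression of 6414 of the 22626 probe sets, 28.3%, changed over the 5 days (limma moderated F-test, Benjamini-Hochberg adjusted p below 0.05), and these represented 3833 named genes. The first principal component held 50.6% of the variance and separated the days, from between -59.1 and -54.1 on the day 3 arrays to between 37.0 and 44.8 on the day 15 arrays. The second component, with 9.50% of the variance, was above 0 on the arrays of days 6 and 9 and below 0 on those of days 3 and 12. It spread the day 15 arrays, from -26.4 in replicate 1 to 8.81 in replicate 3. Of the probe sets that changed, 3078 had their highest mean on day 3, 1522 on day 15 and 919 on day 12, while 408 peaked on day 6 and 487 on day 9. With scan day, which held arrays of several days, as a block, 6074 probe sets passed. With the fluidics module as a block 3837 passed and 1681 of them peaked on day 3. However, all 3 day 3 arrays were processed on module 1, so that this block cannot be fully separated from day.

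**Figure D1:**
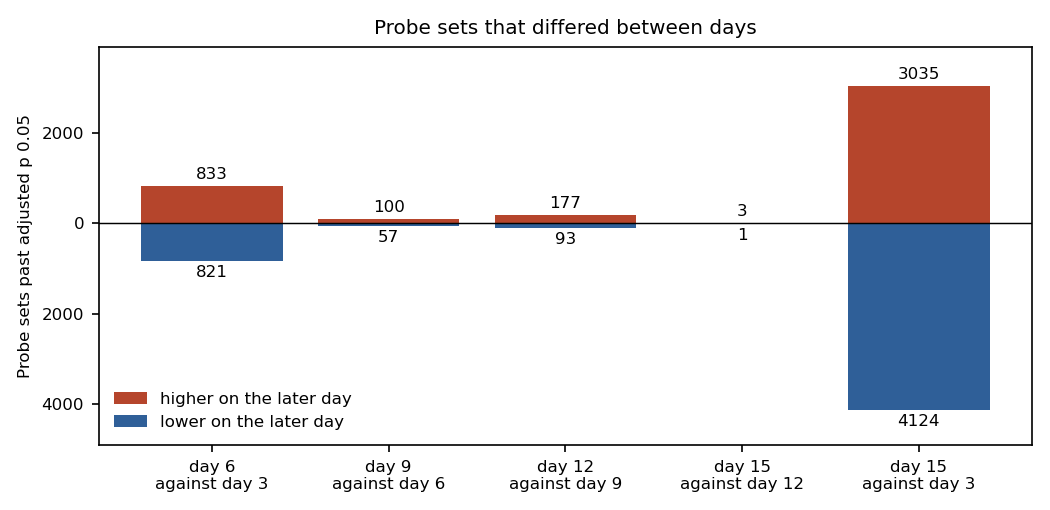
Number of probe sets that were higher (upward bars) or lower (downward bars) on the later day in each comparison, at an adjusted p below 0.05 with 3 arrays a day. The interval from day 3 to day 6 had 833 higher and 821 lower probe sets, and the interval from day 12 to day 15 had 3 and 1.

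From day 3 to day 15, genes of macrophages, lysosomes, interferon responses and fibrous matrix rose, while genes of skeletal muscle, limb patterning and the cell cycle fell. As lists, fibrous matrix (adjusted p = 0.17), S phase (0.26) and G2 and mitosis (0.28) did not hold with an estimated correlation. Of 29 measured genes of macrophages and osteoclasts, the bone-resorbing cells of the same lineage, 27 rose and none fell, with a median change of 3.17 (27 also when adjusted over the list alone). Fcer1g, a signalling subunit of Fc receptors, went from a signal of 26.5 ± 9.27 to 848 ± 230 (SD, n = 3 on each day), a 20.2-fold rise (adjusted p = 7.45e-09). Mrc1, the macrophage mannose receptor, rose 18.6-fold, from 30.8 ± 7.82 to 866 ± 225 (adjusted p = 1.68e-08). The lysozyme genes Lyz1 and Lyz2 rose 44.8-fold and 28.0-fold, though their near-identical sequences leave the share of each uncertain. The osteoclast genes Ocstamp and Calcr did not pass (changes of 0.07 ± 0.26 and 0.14 ± 0.15, SE). Among 25 lysosomal genes 23 rose, with a median of 1.00 (24 adjusted over the list alone), led by the proteases Lgmn (2.53 ± 0.14) and Ctsh (1.84 ± 0.10). Among 26 interferon-response genes 23 rose and none fell, with a median of 1.33 (23 adjusted over the list alone). The class I antigen H2-D1 rose by 3.00 ± 0.15 (with 7 of its 8 other probe sets) and the immunoproteasome subunit Psmb8 by 3.09 ± 0.30, while Mx1 changed by 0.23 ± 0.14 without passing. Ifi27l2a, an interferon-induced gene, rose 24.6-fold from 4.43 ± 0.513 to 513 ± 210.

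Many extracellular matrix genes rose from day 3 to day 15, while others fell or did not pass. In camera with an estimated correlation, fibrous matrix (adjusted p = 0.17), cartilage matrix (0.43), hypertrophy and mineralisation (0.43) and collagen processing (0.18) did not hold as lists. Of 26 genes of tendon, perichondrium and fibrous matrix, 20 rose and 3 fell from day 3 to day 15, with a median of 1.06 (21 and 3 adjusted over the list alone). The thrombospondin Thbs4 rose by 3.98 ± 0.31 and the small proteoglycan decorin, Dcn, by 3.32 ± 0.24, while the tendon transcription factor Scx fell by 0.92 ± 0.14 and elastin, Eln, fell by 0.60 ± 0.20 (adjusted p = 0.034, but 0.12 with scan day as a block, where the change was -0.58 ± 0.25, and 0.136 without day 3 replicate 2). Of 22 cartilage matrix genes 8 rose and 2 fell (8 and 3 adjusted over the list alone), with a median of 0.21. Comp, a cartilage and tendon matrix protein, rose 19.8-fold from 73.6 ± 6.41 to 1759 ± 77.2 and the proteoglycan Epyc by 3.17 ± 0.20, but the collagen IX chain Col9a3 fell by 3.05 ± 0.36 (with 1 of its 2 other probe sets) and Mia by 1.28 ± 0.31. Among 22 genes of hypertrophy and mineralisation 10 rose and 1 fell, with a median of 0.61 (11 and 1 adjusted over the list alone). Ibsp, the bone sialoprotein gene, rose 51.5-fold from 0.967 ± 0.551 to 1042 ± 824, and the collagenase gene Mmp13 rose 27.8-fold from 4.67 ± 1.76 to 617 ± 366. Replicate 2 was the highest for both on day 15, at 1986 for Ibsp and 1039 for Mmp13. The 1 member that fell was the cell-cycle inhibitor Cdkn1c, by 1.70 ± 0.20. Of 25 matrix-degrading enzymes and their inhibitors 14 rose and 1 fell (16 and 1 adjusted over the list alone). The cathepsin Ctss rose by 3.37 ± 0.20, and Mmp11 fell, with a change of -1.37 ± 0.14. Of 21 collagen-processing genes 11 rose and 1 fell (the same numbers adjusted over the list alone), P4ha1, a collagen prolyl hydroxylase subunit, by 1.56 ± 0.24. Outside the lists, the extracellular superoxide dismutase Sod3 rose 20.4-fold from 4.43 ± 1.63 to 406 ± 92.6.

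Genes of the muscle lineage fell the most. Of 26 skeletal muscle genes 21 fell and none rose from day 3 to day 15, with a median of -3.19 (21 adjusted over the list alone). The myosin light chain Myl1 went from 948 ± 3.35 to 3.27 ± 2.24, a 50.3-fold fall (adjusted p = 1.94e-08), and Mylpf, Actc1, Tnni1, Myh3, Tnnc2, Tnnc1 and the muscle transcription factor Myog fell between 22.1-fold and 34.9-fold. Myf6 and Des did not pass, with changes of 0.16 ± 0.15 and 0.26 ± 0.16. The neural genes Bex1 and Nnat fell 27.2-fold and 22.8-fold. Of 41 genes of limb bud patterning and mesenchyme 22 fell and 1, the BMP antagonist Grem1, rose by 1.14 ± 0.21. Among those that fell were Msx2 (-1.99 ± 0.15) and Hmga2 (-1.98 ± 0.32), and the list median was -0.61 (24 lower and 1 higher adjusted over the list alone). Of 28 S-phase genes 23 fell and none rose, with a median of -0.98 (25 adjusted over the list alone). Of 29 genes of G2 and mitosis 23 fell and none rose, with a median of -0.85 (23 adjusted over the list alone). Both lists fell least in replicate 3. The medians in replicates 1, 2 and 3 were -1.48, -0.91 and -0.71 for S phase. For G2 and mitosis they were -1.22, -0.82 and -0.43. Uhrf1, which acts in the copying of DNA methylation, fell by 1.58 ± 0.25 and the mitotic kinase Bub1 by 1.37 ± 0.21. Of 18 cholesterol synthesis genes 15 fell (15 adjusted over the list alone), Fdps by 1.84 ± 0.37 (its other probe set did not pass) and Idi1 by 1.81 ± 0.31, with a list median of -0.80. In replicates 1, 2 and 3 the list median was -1.19, -0.81 and -0.39.

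In the test of lists against all other genes (limma camera with a preset correlation of 0.01, adjusted over 34 lists and 5 comparisons), 18 lists were called from day 3 to day 15, 11 higher and 7 lower. With a correlation estimated for each list 6 held: lysosome (adjusted p = 0.00257), matrix-degrading enzymes (0.0161), macrophage and osteoclast (0.0348), skeletal muscle (0.0348), limb bud patterning (0.0491) and interferon response (0.0495). The adjusted p with an estimated correlation was 0.43 for cartilage matrix, 0.43 for hypertrophy and mineralisation, 0.18 for collagen processing, 0.17 for fibrous matrix, 0.26 for S phase, 0.28 for G2 and mitosis and 0.28 for cholesterol synthesis. All 18 lists were also called, in the same direction, with scan day as a block, and their medians had the same sign in all 3 replicates. In that fit the medians were 3.13 for macrophage and osteoclast, 0.87 for lysosome, 1.24 for interferon response, 1.15 for fibrous matrix, 0.41 for cartilage matrix, -3.23 for skeletal muscle, -0.60 for limb bud patterning and -1.11 for S phase. Replicates 1 and 2 had their day 3 and day 15 arrays on one scan day each, and there the macrophage and osteoclast medians were 2.68 and 3.17, the lysosome medians 1.00 and 0.88, the interferon medians 1.15 and 1.01, and the skeletal muscle medians -3.27 and -3.04.

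Of single probe sets, 7159 differed between day 3 and day 15, 3035 higher and 4124 lower on day 15, and 1139 and 858 of them by at least 2-fold (limma, adjusted p below 0.05). With scan day as a block 6621 differed. Of the probe sets called without the day 3 and day 15 arrays of replicate 1, 95.9% moved the same way within its scan day. Of those called without the replicate 2 arrays of these days, 96.8% did.

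**Figure D2:**
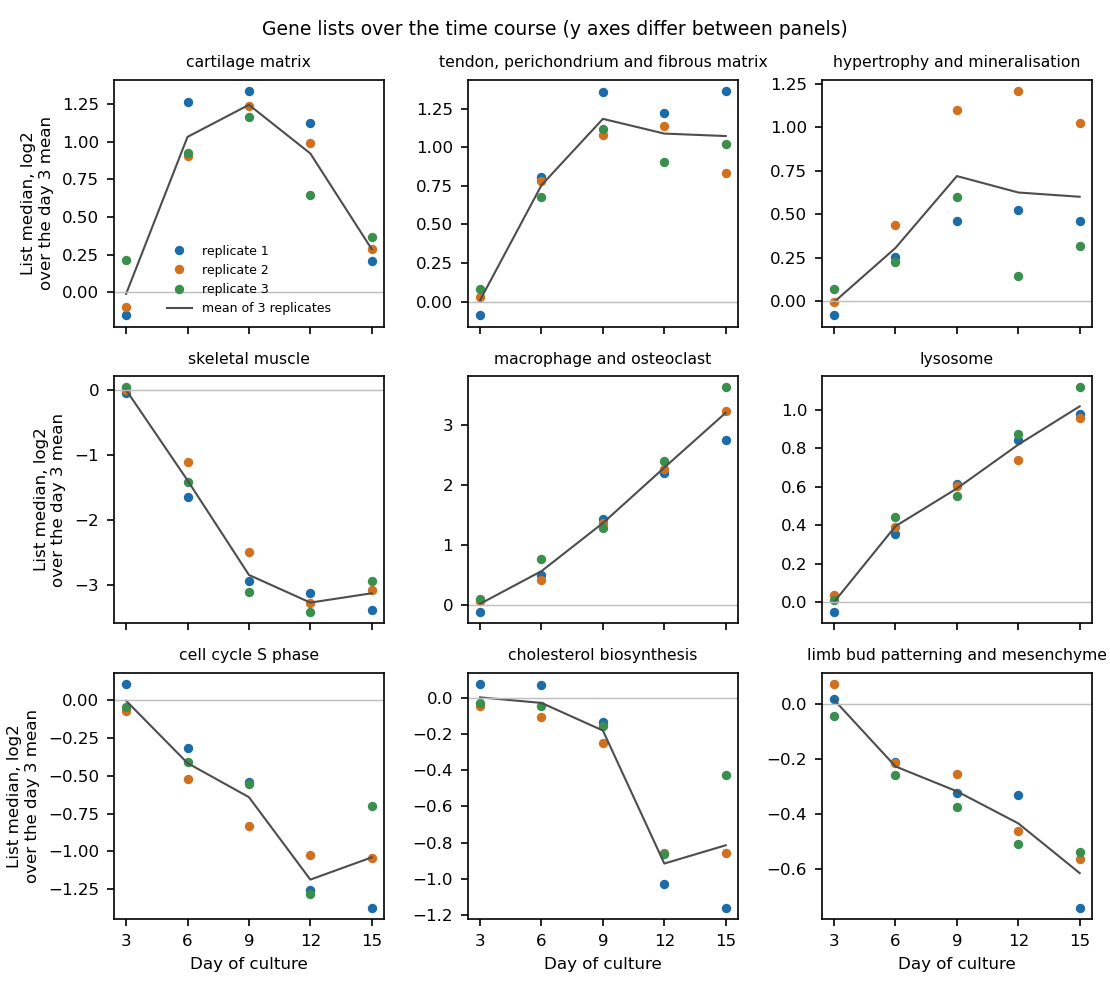
Median log2(signal + 16) of 9 gene lists on each array, relative to each gene's day 3 mean, against the day of culture (points, 1 per replicate; line, mean of 3 replicates; y axes differ between panels). Changes given here are medians of the genes' changes between days, which can differ from changes in the plotted array medians. From day 3 to day 15 the macrophage and osteoclast list rose (median change 3.17) and the skeletal muscle list fell (-3.19). The cartilage matrix list rose from day 3 to day 6 (median change 1.09) and lay lower on day 15 than on day 12 (-0.39). Both cartilage matrix calls did not hold in camera with an estimated correlation (adjusted p = 0.0501 and 0.173).

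Between day 3 and day 6, cartilage and fibrous matrix genes rose and muscle genes fell. As lists, cartilage matrix (adjusted p = 0.0501) and fibrous matrix (0.075) did not hold with an estimated correlation. Of 22 cartilage matrix genes 14 rose and none fell, with a median of 1.09 (14 adjusted over the list alone). Epyc rose 9.09-fold from a signal of 75.8 ± 9.00 to 833 ± 203 (SD, n = 3; adjusted p = 1.07e-06) and Comp by 2.71 ± 0.12 (SE), while Chad and Col9a1 did not pass (-0.32 ± 0.27 and 0.27 ± 0.22). The collagen II gene Col2a1 rose by 0.68 ± 0.17 (adjusted p = 0.0246, but 0.107 with scan day as a block, where the change was 0.70 ± 0.21, and 0.109 without day 3 replicate 1). Of 26 fibrous matrix genes 16 rose and 1, Scx, fell by 0.61 ± 0.14 (17 and 1 adjusted over the list alone), a call that was lost with scan day as a block (-0.57 ± 0.18, adjusted p = 0.121). Dcn rose by 2.09 ± 0.24 and dermatopontin, Dpt, by 2.08 ± 0.20. The cell surface carbonic anhydrase Car9, a well-known hypoxia-inducible gene, rose 14.9-fold from 28.9 ± 9.37 to 652 ± 117, and 8 of 25 genes of glycolysis and hypoxia rose with none lower (14 adjusted over the list alone), including Ndrg1 by 2.13 ± 0.18. Collagen-processing genes rose in 8 of 21 cases (14 adjusted over the list alone), with the lysyl oxidase Loxl3 up by 1.12 ± 0.15. Of 25 matrix-degrading enzymes 8 rose and 1 fell (13 and 1 adjusted over the list alone), and Ctsk, a protease of osteoclasts and fibroblasts, rose by 2.25 ± 0.15. The macrophage and osteoclast list had 9 of 29 genes higher (14 adjusted over the list alone), among them Acp5, the osteoclast acid phosphatase, at 2.27 ± 0.32, and the lysosome list 9 of 25 (17 adjusted over the list alone), among them Hexa at 0.82 ± 0.11. The other genes with the largest rises were S100a4 (8.27-fold), Cpxm2 (7.44-fold) and Clec11a (6.70-fold).

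Skeletal muscle genes fell in 18 of 26 cases with none higher between day 3 and day 6 (20 adjusted over the list alone), Myog from 511 ± 54.5 to 101 ± 28.6 and Myh3 from 474 ± 41.7 to 91.9 ± 13.8. The embryonic globin Hbb-y fell 9.26-fold from 164 ± 85.8 to 2.13 ± 2.48, Nnat 6.02-fold and the epithelial keratin Krt19 4.27-fold. In all, 1654 probe sets differed, 833 higher and 821 lower on day 6, and 236 and 136 of them by at least 2-fold (limma, adjusted p below 0.05). Of the 18 lists called, 12 were higher and 6 lower on day 6. With an estimated correlation 4 held, lysosome (adjusted p = 0.00882), matrix-degrading enzymes (0.018), skeletal muscle (0.0242) and collagen processing (0.042), while the adjusted p was 0.117 for glycolysis and hypoxia and 0.173 for macrophage and osteoclast. In a fit with scan day as a block 17 of the 18 lists were called, all but oxidative phosphorylation, and the medians were 0.96 for cartilage matrix and -1.36 for skeletal muscle. Replicate 2 had both arrays on one scan day, with medians of 0.98 and -1.09 for these lists. Of the 604 probe sets called without those arrays, 98.2% moved the same way in that replicate. The balance moved with the pseudocount, to 712 higher and 473 lower at 1 and to 801 higher and 1096 lower at 64. The number of probe sets fell to 834 with scan day as a block and to 490 with the fluidics module as a block. It was 847, 1056 and 1100 without replicates 1, 2 and 3 of day 3, and 987 and 943 without replicates 2 and 3 of day 6.

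From day 6 to day 9 the fall of muscle genes continued and lysozyme and other macrophage genes rose. Skeletal muscle genes fell in 15 of 26 cases, with a median of -1.24 (16 lower and 1 higher adjusted over the list alone). Myl1 fell 8.59-fold from 356 ± 97.1 to 30.5 ± 25.05 (SD, n = 3; adjusted p = 0.000151), Actc1 6.71-fold, Tnni1 6.65-fold, Mylpf 5.83-fold and Tnnt2 5.20-fold. Of the 29 macrophage and osteoclast genes 6 rose, with a median of 0.84 (18 adjusted over the list alone). Lyz1 rose 5.88-fold from 281 ± 167 to 1601 ± 374 and Lyz2 5.20-fold from 282 ± 118 to 1478 ± 238, and 1 of the other 2 probe sets of Lyz1 also passed. Acp5 changed by -0.34 ± 0.32 (SE) without passing. Selenop, the plasma carrier of selenium, rose 3.10-fold from 283 ± 33.5 to 914 ± 155. The prostaglandin-degrading enzyme Hpgd rose 2.91-fold, but its other probe set did not pass. Comp rose 2.93-fold from 569 ± 36.5 to 1703 ± 210, and with Chad (1.43 ± 0.27) it was among 3 of 22 cartilage matrix genes that rose (4 adjusted over the list alone). Fibrous matrix genes rose in 4 of 26 cases (8 higher and 1 lower adjusted over the list alone), with Dcn up by 1.33 ± 0.24. Lysosomal genes rose in 2 of 25 cases (7 adjusted over the list alone), Lgmn by 0.74 ± 0.14 and Ctsh by 0.62 ± 0.10, and 1 of 26 interferon-response genes did, Bst2 by 0.87 ± 0.18 (13 adjusted over the list alone). In the fit with scan day as a block the adjusted p of Chad, Dcn, Lgmn, Ctsh and Bst2 lay above 0.05, with changes of 1.35 ± 0.39, 1.45 ± 0.27, 0.85 ± 0.15, 0.67 ± 0.14 and 1.08 ± 0.21, whose standard errors were larger than without the block. Those of Chad, Dcn, Lgmn, Bst2 and Hpgd lay above 0.05 without day 6 replicate 1.

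Between day 6 and day 9, 157 probe sets differed, 100 higher and 57 lower on day 9, and 58 and 31 of them by at least 2-fold (limma, adjusted p below 0.05). Of 15 lists called, 4 held with an estimated correlation: lysosome (adjusted p = 0.00882), skeletal muscle (0.0102), macrophage and osteoclast (0.0424) and matrix-degrading enzymes (0.0424). The adjusted p with an estimated correlation was 0.339 for cartilage matrix, 0.187 for fibrous matrix and 0.0885 for interferon response. Of the 15 lists, 8 were called with scan day as a block, and the medians were -1.21 for skeletal muscle and 1.02 for macrophage and osteoclast. Within the scan day of replicate 2 these medians were -1.21 and 0.92. Of the 52 probe sets called without its day 6 and day 9 arrays, 50 moved the same way in that replicate. The 157 probe sets became 76 with scan day as a block and 58, 23 higher and 35 lower, with the fluidics module as a block. They were 62 and 90 without replicates 1 and 2 of day 6, 87 and 92 without replicates 1 and 3 of day 9, and 236 without day 15 replicate 1.

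Between day 9 and day 12 macrophage genes were higher as a list, while most calls of single genes were lost without day 12 replicate 3, and all of them with scan day as a block. The cell cycle and cholesterol synthesis lists were lower, and the immediate early and cytokine lists higher, at the preset correlation and in fry, which compares a list with no other genes (adjusted p between 0.00156 and 0.0125). With an estimated correlation these lists did not pass, and the adjusted p was 0.173 for S phase, 0.173 for G2 and mitosis, 0.075 for cholesterol synthesis, 0.104 for immediate early genes and 0.094 for complement, acute phase and cytokines. Of 28 S-phase genes 5 fell, with a median of -0.63 (20 adjusted over the list alone), and of 29 genes of G2 and mitosis 2 fell, with a median of -0.54 (17 adjusted over the list alone). The mitotic regulator Cdc20 fell by 0.88 ± 0.17 (SE), though neither of its 2 other probe sets passed, and the replication helicase subunit Mcm5 changed by -1.07 ± 0.32 without passing. Cholesterol synthesis genes fell in 7 of 18 cases, with a median of -0.71 (15 adjusted over the list alone). Idi1, an isoprenoid isomerase, fell 2.88-fold from 324 ± 64.4 to 104 ± 33.6 (SD, n = 3; adjusted p = 0.0385), though its other probe set did not pass. Of 24 immediate early genes 3 rose, with a median of 0.57 (14 adjusted over the list alone), led by Fos, 2.83-fold from 154 ± 33.6 to 480 ± 178. Of 22 complement, acute phase and cytokine genes 3 rose, with a median of 0.67 (9 adjusted over the list alone), among them the chemokines Cxcl1, 4.49-fold from 27.8 ± 8.19 to 183 ± 48.1, and Cxcl5. On day 12 replicate 3 stood apart for this list, with a median log2 level over the day 3 mean of 2.24, against 0.82 and 0.86 in replicates 1 and 2. The median change was 0.51, 0.21 and 0.77 within replicates 1, 2 and 3. The macrophage and osteoclast list had 10 of 29 genes higher, with a median of 0.85 (20 adjusted over the list alone), including Cd53 at 1.57 ± 0.18 and Trem2, 3.26-fold higher by 1 of its 2 probe sets. The stress-response gene Gadd45a rose 5.12-fold from 60.4 ± 12.7 to 372 ± 27.8, the carbonic anhydrase Car6 5.88-fold from 49.4 ± 30.4 to 353 ± 103, and the epidermal gene Cdsn 3.66-fold. The secreted protein gene C1qtnf3 fell 3.14-fold from 271 ± 28.8 to 78.9 ± 30.9, the imprinted gene Peg3 2.20-fold (with 1 of its 2 other probe sets), the angiotensin receptor Agtr2 2.18-fold and Hmgb3 2.08-fold.

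Between day 9 and day 12, 270 probe sets differed, 177 higher and 93 lower on day 12, and 77 and 23 of them by at least 2-fold (limma, adjusted p below 0.05). With scan day as a block 0 probe sets passed and 3885 had an unadjusted p below 0.05, against 3424 without the block, and none of the genes named for this interval passed in that fit. The changes of the 270 probe sets all had the same direction there, and were a median of 1.01 times those without the block, but the standard errors were a median of 1.24 times as large, with 6 residual degrees of freedom in place of 10. With the block Gadd45a changed by 3.08 ± 0.54 (SE) against 2.36 ± 0.48 without it, Car6 by 2.83 ± 0.70 against 2.56 ± 0.50, and C1qtnf3 by -1.51 ± 0.23 against -1.65 ± 0.21. Within the scan day of replicate 2, which held both days, 68 of the 76 probe sets called without its day 9 and day 12 arrays moved the same way, with a median of 0.54 of the change in the other replicates. The count was 13 with the fluidics module as a block. Without any one array of days 3, 6, 9 and 12 it lay between 31 (day 12 replicate 3) and 150 (day 6 replicate 2), while it was 808 without day 15 replicate 1 and 583 without day 15 replicate 3. Of the genes named for the interval, C1qtnf3, Cd53 and Trem2 passed without each array in turn, and each of the others had an adjusted p above 0.05 without day 12 replicate 3. Of 13 lists called, 2 held with an estimated correlation, lysosome (adjusted p = 0.0281, median 0.18) and macrophage and osteoclast (0.0462). Of the 13 lists, 11 were called with scan day as a block, with medians of -0.76 for S phase, -0.65 for G2 and mitosis, -0.82 for cholesterol synthesis, 0.88 for immediate early genes, 0.66 for complement, acute phase and cytokines and 0.57 for macrophage and osteoclast. Within the scan day of replicate 2 these medians were -0.34, -0.48, -0.56, 0.43, 0.21 and 0.90.

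Between day 12 and day 15, 4 probe sets differed (limma, adjusted p below 0.05), and 1719 had an unadjusted p below 0.05. With no difference at all, a share of 0.05 of the 22626 probe sets would have such an unadjusted p. Vsig4, a macrophage complement receptor, rose 3.26-fold from 61.3 ± 18.9 to 241 ± 86.4 (SD, n = 3; adjusted p = 0.0459), but its adjusted p lay between 0.0524 and 0.149 without any one array other than day 9 replicate 2 and day 15 replicate 1. The other 3, named after their values were seen, were the white blood cell genes Fermt3 (1.73 ± 0.12, SE) and Il10ra (1.08 ± 0.13), both higher from low signals, and 1 probe set of the growth factor gene Igf2 (-1.56 ± 0.22). The brightest probe sets of Igf2 and Fermt3 changed by -0.35 ± 0.15 and 0.65 ± 0.22 and did not pass, nor did the other probe sets of Fermt3 and Il10ra. As a list, the 29 macrophage and osteoclast genes were higher, with a median of 0.68 (adjusted p = 0.0461 with an estimated correlation), though none passed singly over all probe sets and 17 did adjusted over the list alone. The 25 lysosomal genes were also higher, with a median of 0.20 (adjusted p = 0.0102 with an estimated correlation), none singly and 5 adjusted over the list alone. The 22 cartilage matrix genes were lower as a list, with a median of -0.39, but the adjusted p was 0.173 with an estimated correlation, and none passed singly (2 adjusted over the list alone). Col9a3 had the lowest change of these, -2.25 ± 0.36 (adjusted p = 0.068). The S-phase list was called higher, with a median of 0.17, and the immediate early list lower, with a median of -0.26, but the adjusted p was 0.49 and 0.283 with an estimated correlation. The S-phase median was -0.13, 0.09 and 0.60 in replicates 1, 2 and 3, and it turned to -0.034 with the fluidics module as a block (adjusted p = 0.706). Of the 12 lists called, macrophage and lysosome were the 2 that held with an estimated correlation, and 9 had medians of the same sign in all 3 replicates. In the fit with scan day as a block 5 probe sets differed and 10 of the 12 lists were called. The medians in that fit were 0.76 for macrophage and osteoclast, 0.17 for lysosome and -0.34 for cartilage matrix. Within the scan days of replicates 2 and 3, which each held both days, the medians were 0.74 and 0.86, 0.14 and 0.26, and -0.39 and -0.13. Without day 15 replicate 1, 161 probe sets differed between day 12 and day 15, and without day 9 replicate 2 there were 7. The count was 1 without day 15 replicate 2 or 3, and 2 without replicates 1 or 2 of day 3, day 6 or day 12 or without day 9 replicate 3.

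Markers of cartilage differentiation fixed before the data were examined followed different courses. The cartilage transcription factor Sox9 had a mean signal of 123 ± 20.3 on day 3 and 122 ± 2.00 on day 6 (SD, n = 3), then 70.9 ± 2.20 on day 12 and 65.4 ± 0.862 on day 15, and it changed over the time course (limma F-test, adjusted p = 0.000204). The collagen gene Col2a1 rose from 1245 ± 149 on day 3 to 2009 ± 313 on day 6, was at 2106 ± 98.8 on day 9 and 1265 ± 250 on day 15 (adjusted p = 0.00534). Acan, the gene of the large cartilage proteoglycan, rose from 88.6 ± 27.2 to 238 ± 36.2 between day 3 and day 6 and was at 107 ± 23.7 on day 15 (adjusted p = 0.000573). Mmp13 and Ibsp, genes of late cartilage and bone, changed over the time course (adjusted p = 6.40e-05 and 0.000342), and in both replicate 2 had the highest signal on days 6, 9, 12 and 15. Ibsp on day 9 was at 1995 in replicate 2, 360 in replicate 1 and 168 in replicate 3. The F-test did not call the hypertrophic collagen Col10a1 (104 ± 20.5 on day 3 and 79.8 ± 24.2 on day 15, adjusted p = 0.37), Ihh (0.944), Pth1r (0.538), Alpl (0.096) or the proliferation marker Mki67 (0.0645). For Alpl, day 15 against day 3, the change was 1.86 ± 0.71 (SE), upward in each of the 3 replicates, and its adjusted p was 0.060, but 0.0221 and 0.0362 with scan day and the fluidics module as a block. Alpl was at 417 in replicate 2 on day 9, against 76.2 and 51.1 in replicates 1 and 3. Mki67 was lower on day 15 than on day 3 in the comparison of those days alone, at 157 ± 68.1 against 284 ± 52.3 (adjusted p = 0.0216), but its adjusted p was 0.1 without day 15 replicate 1 and 0.0744 without day 3 replicate 1.

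**Figure D3:**
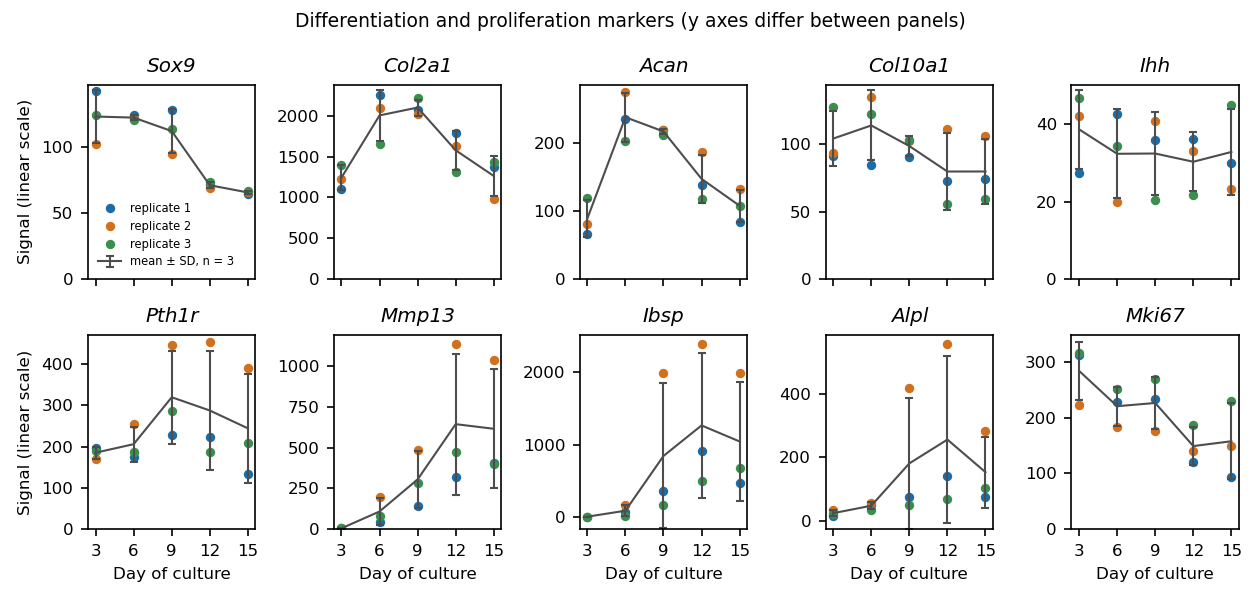
Signal of 10 differentiation and proliferation markers on each array against the day of culture (points, 1 per replicate; line and bars, mean ± SD, n = 3; linear y axes that differ between panels). Col2a1 and Acan were highest on days 6 and 9, Sox9 was lower on days 12 and 15 than before, and replicate 2 lay above the other replicates for Mmp13 and Ibsp from day 6 onward.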

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

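All settings here were chosen before the data were examined. The counts of probe sets past an adjusted p of 0.05 stayed within 1.5 times the reported value under most settings, except in the last intervals. From day 9 to 12 and from day 12 to 15, most settings moved the count further, once leaving out single arrays is included. The larger moves follow, and where no cause is given, the cause was not tested. With the fluidics module as a block, 3837 probe sets changed over time, 1681 of them highest on day 3, and 490, 58 and 13 differed in the intervals from day 3 to 6, 6 to 9 and 9 to 12. All 3 day 3 arrays were on module 1, and module 4 held only arrays of days 12 and 15, so the block is partly day. Module 3 held only day 9 replicate 2, so that array carries no weight in that fit. With scan day as a block the same intervals had 834, 76 and 0. A pseudocount of 1 gave 93 from day 6 to 9, 31 from day 9 to 12 and 1 from day 12 to 15, and a pseudocount of 64 gave 15 in the last. Median centring gave 19 from day 12 to 15, 15 higher and 4 lower, and quantile normalization 3, all higher, against 3 higher and 1 lower. Leaving out the dimmer probe sets gave 437 from day 9 to 12 and 7 from day 12 to 15. With only the 6 arrays of the days compared, the counts were 85, 163 and 0 in the last 3 intervals. That fit has fewer arrays for the spread. The 15-array fit had 1719 at an unadjusted p below 0.05 in the last of these intervals, and part of that number arises with no difference. Of the 76 called list tests, 18 held with an estimated correlation. Fry, which tests whether the genes of a list move one way and compares them with no others, called 18 of 18 of these lists in the same direction from day 3 to 15, and 15 of 18, 6 of 15, 12 of 13 and 7 of 12 in the shorter intervals.

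Leaving out single arrays gave 5110 to 6646 probe sets that changed over time, with 2379 to 3070 highest on day 3, and 5895 to 7138 for day 15 against day 3. The shorter intervals in order of time had 847 to 1983, 62 to 236, 31 to 808 and 1 to 161. The low ends came without day 3 replicate 1, day 6 replicate 1, day 12 replicate 3 and day 15 replicate 2, and all 4 high ends without day 15 replicate 1. List calls ranged from 75 to 81, and 42 to 51 of the 51 changes named as the largest, which lie in 40 genes, passed.

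The direction of 5 list tests against other genes turned, and in 3 of them the list's median also changed sign. With the module as a block these were immediate early genes from day 3 to 6 (median -0.16) and S phase from day 12 to 15 (-0.034), and with scan day as a block ribosomal protein genes from day 6 to 9 (-0.11). The medians kept their sign for S phase from day 6 to 9 with the module as a block (-0.021) and for ribosomal protein genes from day 3 to 6 with scan day as a block (0.16). The cause was not tested.

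The rule set beforehand treated the replicate numbers as sharing only a number. Of 30 same-numbered pairs of arrays, 17 had deviations from the day means that correlated above 0.1. The median was 0.15, against -0.088 for arrays of different days and numbers. All 15 arrays correlated best with their own number, a hint from the data and not from the design. The main fit, without a replicate block, counts such differences between the numbers as spread. The sample titles also carry a code for each number, whose meaning the labels do not give. With a fixed replicate block, 6785 probe sets changed over time, 7469 differed between day 3 and day 15, and 1925, 217, 274 and 5 in the shorter intervals, with 76 list calls. The change of Alpl, day 15 against day 3, was 1.86 and was not called, but passed with the replicate number, scan day or the module as a block (adjusted p = 0.00575, 0.0221 and 0.0362). Signal over background limits the dimmer genes, since low signals shift most with the pseudocount.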

Other observations

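The patterns, explanations and bounds in this part were tested after the results were seen, and the held-out test of the interval from day 9 to day 12 was changed once. Fits without a replicate called only 2, 12 and 0 probe sets, so the 270 with the smallest p in each were taken instead. The gene lists in the next 2 paragraphs were fixed before the data were examined.

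Signalling genes moved in both directions from day 3 to day 15. Of 36 BMP and TGF-beta genes 7 rose and 13 fell (7 and 14 adjusted over the list alone). The BMP antagonist Chrdl1 rose by 2.74 ± 0.20 and Ltbp2 by 2.23 ± 0.20, while Bmp7 fell by 2.87 ± 0.23 and the joint gene Gdf5 by 2.10 ± 0.19 (SE, 3 arrays a day, limma). Of 32 WNT genes 6 rose and 15 fell (6 and 16 adjusted over the list alone). Lgr5 rose by 3.10 ± 0.17, and the receptor Fzd9 fell, with a change of -1.50 ± 0.21. Of 19 FGF genes 2 rose and 5 fell (the same numbers adjusted over the list alone). Fgf7 rose by 2.27 ± 0.21, and Etv4 fell, with a change of -1.70 ± 0.26. Of 13 hedgehog and PTHrP genes 1 rose and 6 fell (1 and 7 adjusted over the list alone), Gli2 by 1.54 ± 0.16 and Gli3 by 0.69 ± 0.15. That list was called lower (adjusted p = 0.0393, but 0.283 with an estimated correlation, and 0.0645 and 0.0592 without replicates 1 and 3 of day 15), and the others were not called. Of 17 IGF genes 6 rose and 3 fell (6 and 3 adjusted over the list alone). Igfbp6 rose by 3.05 ± 0.15, and Igf2r fell, with a change of -1.13 ± 0.15. Among 15 chondrogenic transcription factors 1 rose, Zbtb20 by 1.41 ± 0.14, and 6 fell (the same numbers adjusted over the list alone; list adjusted p = 0.0965), among them Sox5 by 1.36 ± 0.24 (with 1 of its 3 other probe sets) and Shox2 by 1.19 ± 0.22.

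Other cell types and pathways differed in how far they moved from day 3 to day 15. Of 15 adipocyte genes 6 rose and 1 fell (6 and 1 adjusted over the list alone; list adjusted p = 0.00414, and 0.199 with an estimated correlation). Fabp4 rose by 3.94 ± 0.44 (with 1 of its 3 other probe sets) and Lpl by 3.90 ± 0.30, while Slc2a4 fell by 0.49 ± 0.12. Fabp4 and Lpl are also expressed by macrophages. Of 17 nerve and glia genes 3 rose and 7 fell (3 and 7 adjusted over the list alone), Gap43 by 1.93 ± 0.17 and Erbb3 by 1.63 ± 0.14 (its other probe set did not pass). Of 22 complement, acute phase and cytokine genes 11 rose and 1 fell (13 and 1 adjusted over the list alone; list adjusted p = 0.187 with an estimated correlation), C1ra by 3.52 ± 0.17. Of 30 oxidative phosphorylation genes 11 fell and none rose (14 adjusted over the list alone; list adjusted p = 0.308 with an estimated correlation), Cyc1 by 0.87 ± 0.11. Of 24 genes of the unfolded protein response 6 rose and 3 fell (the same numbers adjusted over the list alone; list adjusted p = 0.18), Trib3 by 2.32 ± 0.44 upward and Creb3l2 by 1.02 ± 0.10 downward. Of 25 genes of glycolysis and hypoxia 9 rose and 1 fell (10 and 1 adjusted over the list alone; list adjusted p = 0.283 with an estimated correlation). Of 21 epidermal genes 2 rose and 5 fell (2 and 7 adjusted over the list alone), and of 23 genes of proteoglycan chain synthesis and sulfation 3 rose and 2 fell (3 and 2 adjusted over the list alone), with neither list called. Endothelial genes had a median of -0.02 with 1 of 20 higher and 1 lower (0 and 0 adjusted over the list alone), and erythroid genes a median of -0.06 with 1 of 16 higher and 1 lower (0 and 1 adjusted over the list alone). Smooth muscle and myofibroblast genes (2 higher and 5 lower), cell cycle inhibitors (4 and 1), mast cell genes (1 and 1) and immediate early genes (7 and 2) had the same numbers adjusted over the list alone, and none of these lists was called. None of 17 ribosomal protein genes passed (limma, lowest change -0.29 ± 0.17 for Rps6), and 0 did adjusted over the list alone.

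Random regroupings of the arrays were counted for each result. For the F-test, 1 of 100 regroupings of the 15 arrays into 5 days, the real one, gave as many as 6414 probe sets, and the highest other gave 7. This argues against a random sorting of these arrays into days as the source of that count. It does not test chance differences between cultures, since the replicates may be technical. For the list tests, 4 of 100 regroupings gave as many as 76 calls, the highest other 82. Although that share lies under 0.05, some regroupings gave as many calls at the preset correlation, so the count alone says little, and 18 of the 76 held with an estimated correlation. For pairs of days the 6 arrays have only 10 splits, too few for a share under 0.05. The real split gave the highest count, with 1 of 10 as large, from day 3 to 15 (7159, highest other 0), day 3 to 6 (1654, highest other 0), day 6 to 9 (157, highest other 0) and day 9 to 12 (270, highest other 1). From day 12 to day 15, 3 of 10 splits gave as many as the real 4, the highest other 8.

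The first pattern is the set of differences between day 9 and day 12, none of which passed with scan day as a block, where the changes were a median of 1.01 times and the standard errors 1.24 times those without it. In 2 replicates these days were scanned on different days, so a scan effect was weighed. Probe sets chosen without a replicate were therefore measured in it from day 6 to day 12, whose arrays shared a scan day in every replicate. The signed median change was 1.22, 0.81 and 1.09 in replicates 1, 2 and 3, with a lowest value of 0.813, which argues against scan day as the source of the change by day 12. When it happened stays open: from day 9 to day 12 in replicate 2, the 1 replicate with both arrays on a scan day, the median was 0.395, against 0.784 and 0.831 in the others, so a scan effect on part of the timing cannot be told apart with 1 such replicate.

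The second pattern is the rise of lysosomal and interferon-response genes beside that of macrophage genes, for which a growing share of myeloid cells is a candidate explanation. Among genes that rose, in 1 of the 3 lists each and with a day 6 mean of at least 62.9, the median of all signals, the median share of each gene's rise from day 3 to day 15 that was reached by day 6 was compared. It was 24.6%, 35.6% and 28.7% for 22 lysosomal genes in the 3 replicates, and 9.55%, 6.90% and 9.72% for 12 macrophage and osteoclast genes. The difference was at least 15.1 percentage points (19.6 without that bound on signal, with 23 and 27 genes). This argues against a growing share of myeloid cells, of an unchanged mix and with unchanged expression, as the whole source. Myeloid cells whose expression or mix of types changed with time were not tested. For 9 interferon-response genes the smallest difference was 7.82 points (8.38 for 23 genes without the bound on signal), under the limit of 10 points. A growing share of myeloid cells therefore cannot be told apart there. Scan day did not account for the lysosomal rise from day 3 to day 15, whose median was 0.873 with scan day as a block. The shares reached by day 6 crossed scan days in replicates 1 and 3, but not in replicate 2. Lysosome-rich cells that came earlier, osteoclasts among them, stay open. Acp5, the osteoclast phosphatase, had its highest mean signal, 226, on day 6.

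The third pattern is the lower level of cartilage matrix genes after day 9. In a contrast of day 15 with day 9, added after the data were seen, 9 of 22 were lower and none higher, with a median of -0.77, while 1 of 26 fibrous matrix genes was higher and 2 lower, with a median of -0.028. The difference between the lists was 1.14, 0.244 and 0.528 in replicates 1, 2 and 3, with 1 under the bound of 0.3, and it cannot test dilution by fibrous cells themselves, so dilution of cartilage cells cannot be told apart from a change within them. Scan day alone is argued against, since the cartilage median was -1.04 and -0.494 in the 2 replicates with both arrays on one scan day. A change within the cartilage cells was not tested separately.

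A hypothesis came from the falls of Nnat, Peg3 and Cdkn1c, which are all imprinted, that is, expressed from the copy of 1 parent. A list of 30 imprinted genes was written after these falls were seen and before it was tested, and Nnat, Peg3, Cdkn1c and Dcn were left out of the test. Of the other 24 measured genes 14 fell and 1 rose from day 3 to day 15, with a median of -0.58 (limma camera p = 3.13e-05, and p = 0.031 with an estimated correlation). Without Igf2 and Igf2r as well, which are in a fixed list and whose falls had been seen, 12 of 22 fell and 1 rose, with a median of -0.55 (p = 0.000174, and p = 0.0427 with an estimated correlation). Asb4 fell by 2.44 ± 0.14, Slc38a4 by 2.07 ± 0.24, Dlk1 by 2.06 ± 0.17 and Ndn by 1.45 ± 0.19 (with 4 of its 7 other probe sets), while Gatm rose by 1.26 ± 0.22 and Gnas changed by 0.0044 ± 0.14, though 1 of its 3 other probe sets was lower. Peg12, Zim1, Phlda2 and Usp29, which also fell, had mean signals under 62.9, the median of all signals, on both days. Neither of the 2 other probe sets of Grb10, which fell, was lower, nor was the other one of Usp29. The p-values of this added list were not adjusted, unlike those of the fixed lists. The fibrous matrix list, day 15 against day 3, had an unadjusted camera p of 0.0368 with an estimated correlation. Adjusted, that was 0.17, and the list did not hold. Imprinted genes may be lower as a group on day 15, but this was not tested at the adjustment used for the fixed lists. It says nothing of imprinting itself, since many imprinted genes are also markers of muscle or growing mesenchyme and the test did not separate these.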
